A study of Homo sapiens with 6 samples.

How the data were processed

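Circular RNAs (circRNAs), closed RNA rings formed by back-splicing, were measured on 6 one-colour Agilent microarrays of THP-1 cells, an established human monocytic leukaemia line. Per the labels' protocols, all cells were differentiated into adherent macrophages with 100 nM phorbol 12-myristate 13-acetate (PMA) for 48 h. The 3 oxLDL samples were then exposed to oxidised low-density lipoprotein (oxLDL) at 50 mg/ml for 24 h. The concentration and unit are printed as the labels state them; the value is unusually high for oxLDL, and whether the unit is right could not be checked here. As the design text describes it, the control group received PMA for 48 h and nothing more, and its time of collection is not stated further. If controls were collected after those 48 h, the additional 24 h of culture and oxLDL cannot be told apart. Samples were grouped by the treatment in their titles and carry the replicate numbers given there. The design text calls them independent experiments.

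RNA was depleted of ribosomal RNA, amplified by random priming and labelled with Cy3, per the labels' protocols. The deposited scanner files hold spot intensity values that the authors extracted with Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes. Per the file headers, the processed signal is the background-subtracted and detrended intensity of each spot, and no scaling between arrays had been applied. The files also hold other columns that the authors deposited, flags of 0 or 1 per spot for signal well above background, saturation and outlying pixels. A value table that the authors deposited holds a log2 value for each of 5397 circRNA probes on each array. Its column medians were 5.17, 5.16 and 5.15 for control replicates 1 to 3 and 5.18, 5.17 and 5.14 for oxLDL replicates 1 to 3. Each column rose with the background-subtracted median signal of its own array (Spearman correlation across probes of 0.99987 at the lowest, where the array that came nearest otherwise reached 0.914), which settles the direction. Over the brighter detected probes each column was close to a straight line in log2 of that signal (Pearson r of 0.996 at the lowest, slopes of 0.867 to 1.26), as values on a log2 scale would be after normalization between arrays. The exact normalization behind the table and a small offset stay unknown.

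Each array carried 15743 spots, of which 536 control spots of the array maker were left out. The rest were 5397 circRNA probes (4190 on 3 spots and 1207 on a single spot) and 143 further probes on 10 spots each, among them 50 probes for linear mRNAs. The circRNA probes carry only the array maker's identifiers, and no table used here pairs these with a circRNA, a host gene or a class of circRNA. The planned analyses of 19 host gene lists, of circRNA classes, of circRNAs that share a host gene and of 9 widely studied circRNAs were therefore not run. The mRNA probes carry RefSeq accessions, and all 50 were matched to a gene symbol through a RefSeq table of assembly GRCh38.p14, which was used for names only because the array design was built on another assembly.

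The scaled signal was log2 of the processed signal minus the array's 75th percentile of it over all non-control spots. Outlier spots were left out (286 to 315 of 15207 per array), no spot was saturated, and spots of a probe were averaged. A probe counted as well above background on an array when at least 0.5 of its spots did. Probes well above background on at least 3 of the 6 arrays were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment at 0.05. A second list took probes at an unadjusted p under 0.05 with a change of at least 1.5-fold. The 12 mRNA probes that met the same filter were fitted together with the circRNA probes, and their p-values were adjusted over these 12; this comparison was added after the data were examined, because these are the probes with gene names. Values per array were compared by exact permutation tests over 20 assignments, whose smallest two-sided p is 0.1.

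Where a probe was not well above background on any array of a group, a bound is given: the brighter group's mean against, on each array of the dimmer group, the higher of the lowest signal among spots well above background and the probe's own signal. This bound concerns the means of these arrays and leaves out their sampling error. The rule for named probes was fixed before the data were examined. It takes probes whose 3 values in a group all lie above the 3 of the other and that are well above background on all 3 arrays of the brighter group. With fewer than 5 per direction past the threshold, it fills up to 5 with the smallest unadjusted p among probes changed at least 1.5-fold. Without names, the 2 largest changes per direction are printed. The named mRNA probes are all 12 that were tested.

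The fit was tested on simulated arrays with the means of 1894 probes and 200 changed probes. With the spread of the real arrays, it recovered 4% of 2-fold, 36% of 4-fold, 64% of 8-fold and 88% of 16-fold changes past the adjusted threshold. With a spread of 0.1 (log2) between arrays it recovered 100% at each of these sizes. The simulated noise was independent between probes, while the real arrays shared differences across many probes, so these rates need not hold for the real arrays. The number of arrays and the spread between them limit the precision of every value. Alternatives set before the data were examined covered scaling, background correction (normexp with an offset of 50, on median signals), the filter on dim probes, outlier spots, the variance model, array weights, the replicate number and the position on the slide as blocks, the authors' value table, the threshold and each replicate left out. The fit without both control replicate 3 and oxLDL replicate 1 and the fit within slide row 1 were added after the data were examined. All arrays share a scan time, so scan was not a batch. The arrays lay in 2 rows and 4 columns. Row 1 held the 3 oxLDL arrays and control replicate 1, and row 2 held controls only. Column 1 held control replicate 2 and oxLDL replicate 1, column 2 held control replicate 3 and oxLDL replicate 2, and the other columns held a single array each.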

Results

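The abundance of circRNAs was measured in PMA-differentiated THP-1 macrophages with and without exposure to oxLDL, the modified lipoprotein that macrophages take up as they become foam cells. Each group had 3 arrays. Of 5397 circRNA probes, 1017 were well above background on all 6 arrays, 2871 on none, and 1900 on at least 3 and thus tested. On the control arrays, 29.8%, 35.3% and 27.5% of the circRNA probes were well above background in replicates 1 to 3, and on the oxLDL arrays 40.1%, 28.8% and 33.0%. The mean share was 30.9% ± 4.04 (SD, n = 3) in the control group and 33.97% ± 5.69 (SD, n = 3) in the oxLDL group, a difference within the spread between arrays (exact permutation test, two-sided p = 0.6, adjusted p = 0.7 over 6 array measures). The bright end of the signal differed more: the processed circRNA signal that 1% of the probes exceed was 1511 ± 436 (SD, n = 3) in controls and 5917 ± 4782 (SD, n = 3) with oxLDL. All 3 oxLDL arrays lay above all 3 control arrays, with oxLDL replicate 3 at 11251 and oxLDL replicate 2 at 2015, just above control replicate 2 at 2014 (exact permutation test, two-sided p = 0.1, the smallest this design allows, adjusted p = 0.4).

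The comparison of oxLDL with control asked which circRNAs change when these macrophages are loaded with oxLDL. The circRNA probes with the strongest signal had higher group means with oxLDL: among the 190 brightest of the tested probes, 174 had a log2 fold change above 0, with a median of 0.72, while the 950 dimmest probes had a median of -0.01. The median scaled log2 signal of these 190 probes was 4.94, 5.25 and 5.28 on control arrays 1 to 3 and 5.82, 5.38 and 6.86 on oxLDL arrays 1 to 3. Scalings that give every array the same range of signal remove such a drift by construction, so they do not decide whether it came from oxLDL. Of the 190, 87 were above 0 with quantile normalization and 94 with cyclic loess. In the authors' value table, whose normalization is unknown, 84 were above 0, with a median of -0.097. With the slide column as a block 134 were above 0, with a median of 0.28. Without oxLDL replicate 3 the median of these probes was 0.32. No single circRNA probe passed the threshold in limma's moderated test (0 of 1900 at a Benjamini-Hochberg adjusted p under 0.05, lowest adjusted p 0.998). At an unadjusted p under 0.05 there were 22 probes, fewer than the 95 that 0.05 of the tested probes would make.

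**Figure D1:**
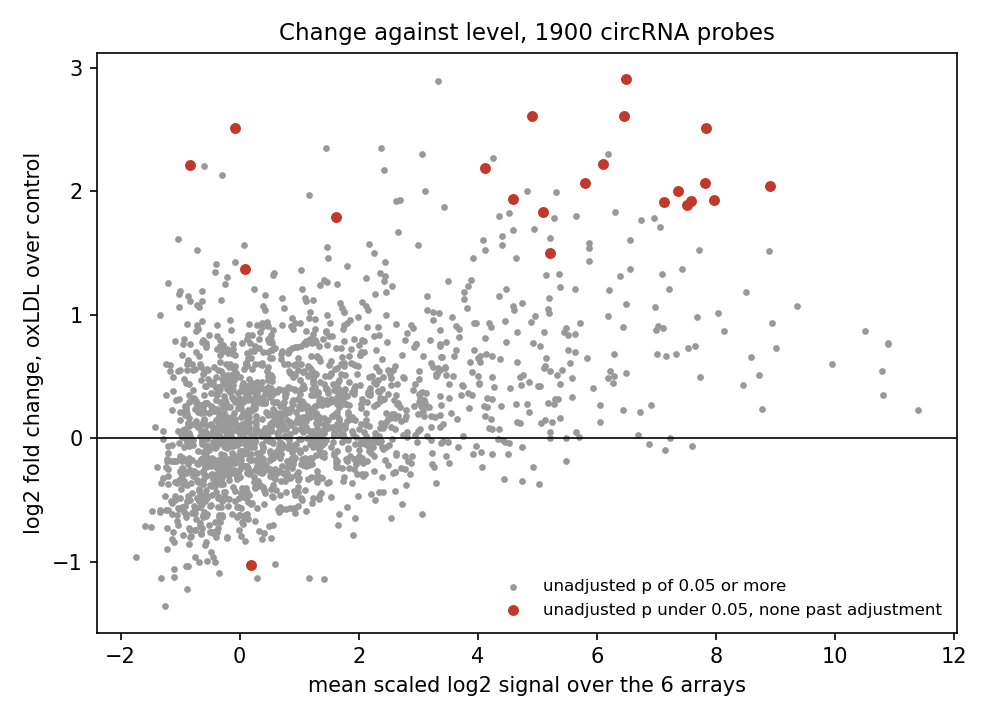
Log2 fold change of oxLDL over control (vertical axis) against the mean scaled log2 signal over the 6 arrays (horizontal axis) for each of the 1900 tested circRNA probes, with the 22 probes at an unadjusted p under 0.05 in red. Of these 22, 21 lie above 0 and 17 belong to the 190 brightest probes. With quantile normalization, which removes it by construction, the upward drift with signal is gone.

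All 22 of these probes differed by at least 1.5-fold, with 21 higher and 1 lower with oxLDL. On lists called afresh under other scalings, that split was 10 higher and 2 lower with quantile normalization, 9 and 3 with cyclic loess, 12 and 5 when arrays were scaled by the median of detected probes, and 10 and 11 when the 75th percentile was taken over detected probes. The 21 probes themselves stayed higher with oxLDL under each of these scalings, which their selection largely fixed in advance, since the smallest of these rises was 1.37. The 2 scalings on detected probes moved all probes by a median of -0.15 and -0.35. Shifts with quantile normalization and cyclic loess had an SD of 0.27 and 0.25 across probes. The median log2 fold change of all tested probes was 0.14 under the scaling used here and -0.21 with the 75th percentile of detected probes, which shifts all probes by nearly the same amount. The 3 oxLDL values all lay above the 3 control values for 68 probes and below them for 37, together 5.53% of the probes, where chance gives 10%. With the slide row as a block 25 probes were on the list, with the slide column as a block 98 (63 higher and 35 lower), and within row 1, which sets the 3 oxLDL arrays against control replicate 1, 52. Both row fits take their differences from that single control array, which is assumed to vary like the other arrays. The column fit rests on columns 1 and 2, which hold both groups, and leaves 1 residual degree of freedom per probe. In both columns the oxLDL array lay in row 1 and the control array in row 2, so this fit cannot separate treatment from row. Within either column a single array stands for each group, which leaves no residual degrees of freedom. In column 1, 64 probes were at least 2-fold higher and 36 at least 2-fold lower with oxLDL, and in column 2, 387 and 46. The authors' value table gave 14 probes (11 higher and 3 lower) and 0 past the adjusted threshold.

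On the side of higher signal with oxLDL, the rule for named probes gave ASCRP001070 and ASCRP001423, and none of the 4 probes named here passed the adjusted threshold. ASCRP001070 had a scaled log2 signal of 5.04 ± 0.99 (SD, n = 3) in controls and 7.95 ± 1.81 (SD, n = 3) with oxLDL, a log2 fold change of 2.91 with a standard error of 0.95 (limma, adjusted p = 0.998). It was 1.87 without oxLDL replicate 3 and 1.30 with the slide column as a block. ASCRP001423 was well above background on 1 of 3 control arrays and on all 3 oxLDL arrays, with a log2 fold change of 2.51 and a standard error of 0.72 (limma, adjusted p = 0.998), a size that rests in part on control values at background and was 1.14 in the authors' value table. On the other side, ASCRP004698 was at 0.70 ± 0.31 (SD, n = 3) in controls and -0.33 ± 0.36 (SD, n = 3) with oxLDL, a log2 fold change of -1.03 with a standard error of 0.44. ASCRP005161 was well above background on all 3 control arrays and on no oxLDL array, which under this scaling makes the control signal at least 1.57-fold that of the oxLDL group (limma, adjusted p = 0.998). With normexp background correction and quantile normalization the log2 fold changes of ASCRP001070, ASCRP001423, ASCRP004698 and ASCRP005161 were 1.95, 0.70, -0.33 and -0.22.

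The arrays differed from each other in ways the treatment groups do not describe. Across 1894 circRNA probes, which are not independent replicates, control replicates 1 and 2 correlated at r = 0.96, and both correlated with oxLDL replicate 1 at 0.94 and 0.97. Control replicate 3 correlated with control replicates 1 and 2 at 0.64 and 0.69, and with oxLDL replicates 2 and 3 at 0.90 and 0.79. The first principal component held 62.8% of the variance, with control replicate 3 at 55.2 at one end and oxLDL replicate 1 at -28.2 at the other. The median standard deviation between arrays was 0.76 (log2) in the control group and 0.63 in the oxLDL group.

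**Figure D2:**
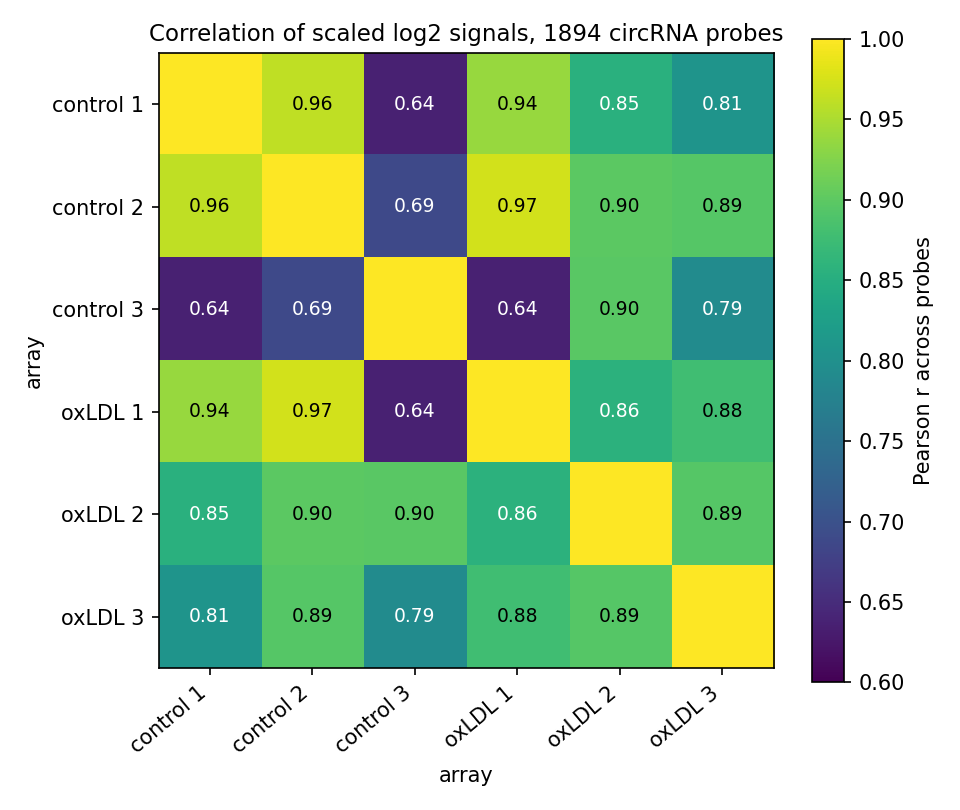
Pearson correlation of the scaled log2 signals of each pair of arrays across 1894 circRNA probes (rows and columns are arrays, colour and printed values give r). Control 3 lies nearer to oxLDL 2 (0.90) than to control 1 (0.64), and oxLDL 1 nearer to control 2 (0.97) than to oxLDL 2 (0.86).

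The mRNA probes carry gene names, but a signal well above background need not come from the named transcript. Of 40 negative sequence probes on the array, 2 were well above background on at least 3 arrays. Of these, normal_negative_0033 was so on all 6, from -1.17 on oxLDL replicate 1 to 0.66 on control replicate 3. All values of *PIMREG*, *SPDL1* and *WRN* lay within that range. Of 50 mRNA probes, 12 were well above background on at least 3 arrays and 32 on none, and none of the 12 differed between oxLDL and control in limma's test (0 at an adjusted p under 0.05, 0 at an unadjusted p under 0.05, lowest adjusted p 0.903). *POLR2A*, which encodes the largest subunit of RNA polymerase II, was at 3.20 ± 0.71 (SD, n = 3) in controls and 3.02 ± 0.53 (SD, n = 3) with oxLDL. *RHOH*, a small GTPase gene of haematopoietic cells, was at 3.01 ± 0.42 and 2.76 ± 0.27 (SD, n = 3 each). *RAD54B*, a DNA repair gene of homologous recombination, had the largest difference, a log2 fold change of 0.85 with a standard error of 1.06, and its oxLDL arrays ranged from 3.31 to 6.99. Its difference was 2.24 within slide column 1 and 1.49 within column 2, and 1.87 with the slide column as a block (limma, adjusted p = 0.0545 over the mRNA probes, with 0.0545 to 0.993 over all alternatives). That block fit rests on columns 1 and 2 and leaves 1 residual degree of freedom per probe. The difference of *RAD54B* was 0.25 with the slide row as a block, and its direction turned without oxLDL replicate 1 (-0.27) and with array weights (-0.083). *SERPIND1*, which encodes the thrombin inhibitor heparin cofactor II, had a log2 fold change of 0.16 ± 0.43 (SE), and *LOXL2*, a lysyl oxidase of collagen crosslinking, of 0.44 ± 0.49 (SE). With a replicate left out, *LOXL2* ranged from 0.091 without oxLDL replicate 3 to 0.68 without oxLDL replicate 1.

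Among the other tested mRNA probes, *CENPE*, a kinetochore motor protein, had a log2 fold change of 0.26 ± 0.66 (SE) and was well above background on 2 control and 3 oxLDL arrays. *SPDL1*, which recruits dynein to kinetochores, had -0.13 ± 0.57 (SE), *WRN*, a RecQ helicase, 0.25 ± 0.43 (SE), and the exonuclease gene *EXO1*, detected on 2 arrays of each group, -0.22 ± 0.96 (SE). *PIMREG* was at 0.19 ± 0.43 (SE) and the zinc finger gene *ZNF195* at 0.08 ± 0.67 (SE). *MOCOS*, which encodes the molybdenum cofactor sulfurase, was well above background on 1 control and 2 oxLDL arrays, with 0.78 ± 0.80 (SE). With a replicate left out, *MOCOS* ranged from 0.31 without control replicate 2 to 1.71 without control replicate 3. It was 1.69 with array weights, 1.37 within slide column 1 and -0.85 within column 2. Control replicates 1 and 2, at -2.60 and -2.62, were not well above background for *MOCOS*, so the size of its rises rests in part on background. For 7 of the 12 tested mRNA probes, every array of the inner slide columns (2 and 3) lay above every array of the outer columns (1 and 4). These were *MOCOS*, *LOXL2*, *CENPE*, *ZNF195*, *SPDL1*, *POLR2A* and *EXO1*. In the inner columns *EXO1* was at 1.99 on control replicate 3, 1.09 on oxLDL replicate 2 and 1.00 on oxLDL replicate 3. In the outer columns it was at -0.51, -0.37 and -1.62 on control replicates 1 and 2 and oxLDL replicate 1. Its difference of oxLDL from control was -1.25 within slide column 1 and -0.90 within column 2, and -1.08 with the slide column as a block, but 0.66 with the slide row as a block, 0.80 with array weights, 0.59 without control replicate 3 and 0.67 without oxLDL replicate 1. The direction of *EXO1* thus turned with the fit.

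**Figure D3:**
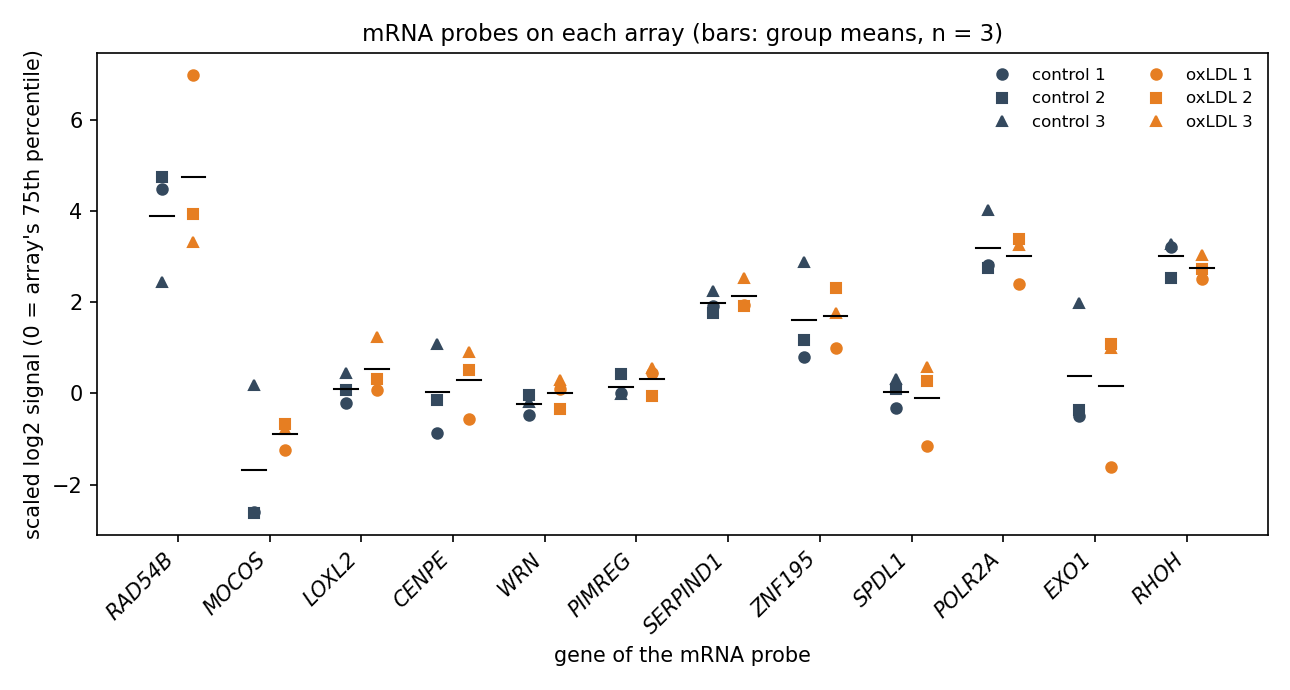
Scaled log2 signal (vertical axis, 0 is the array's 75th percentile) of the 12 tested mRNA probes on each of the 6 arrays, with control arrays in dark blue, oxLDL arrays in orange and group means (n = 3) as bars. For *EXO1*, control 3 at 1.99 lies with oxLDL 2 and 3 near 1, and oxLDL 1 at -1.62 lies below all other arrays.

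Few mRNA probes belong to the gene lists that were fixed before the data were examined. Of all 50 mRNA probes, 32 were not well above background on any array. Nothing here sets a gene that was not expressed apart from a probe with weak signal. The calls below therefore do not show that a gene was absent from the cells. From the cell cycle and DNA replication list 6 genes had a probe; *CENPE* was tested, and *ATAD2*, *BRCA1*, *CCNA2*, *DTL* and *WDHD1* were not well above background on any array. From the list of monocyte and macrophage identity only *SPP1*, the gene of osteopontin, had a probe, and it was not well above background on any array. The same held for *TCF7* and *ZAP70* among markers of lymphocytes and erythroid cells, for *LOX* among markers of muscle, fibroblasts and endothelium, and for *UCHL5* among ubiquitin ligases and proteases. Of the chromatin regulators, *SMARCAD1* was well above background on 1 oxLDL array and *BAZ1A* on none.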

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

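The tests in this part were chosen after the results they concern had been seen. Groups of 3 arrays were too small to look for single outlying arrays. Of 93 spike-in and control-sequence probes outside the comparisons, 21 were well above background on all 3 oxLDL arrays and could be flagged. None of these was above the control arrays on all 3 oxLDL arrays, where chance gives 5%.

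By probe detection and by the sign of the first principal component, the arrays fell into 2 sides. The first held control replicates 1 and 2 with oxLDL replicate 1, and the second held control replicate 3 with oxLDL replicates 2 and 3. In this split 193 circRNA probes were well above background on all 3 arrays of either side and none of the other. The split by treatment gave 5, and any other of the 10 splits at most 74. Pairwise correlations did not place oxLDL replicate 3 clearly. Its r was 0.81 and 0.89 with control replicates 1 and 2 and 0.88 with oxLDL replicate 1, against 0.79 with control replicate 3 and 0.89 with oxLDL replicate 2. An exchange of the labels of control replicate 3 and oxLDL replicate 1 is a candidate explanation, since both are out of place: control replicate 3 had a mean r of 0.66 with its own group and 0.85 with oxLDL replicates 2 and 3, and oxLDL replicate 1 had 0.87 with its own group and 0.96 with control replicates 1 and 2. The bright end of the signal did follow the labels: 1% of the circRNA probes exceeded 1257 on control replicate 3 and 4486 on oxLDL replicate 1. An exchange cannot be told apart from an effect of slide position, because 6 of 6 arrays follow outer (1 and 4) against inner (2 and 3) columns. More linear RNA in the samples of the second side also stays open: the 12 mRNA probes were higher there by a median of 0.78 (log2), at the 92.9th percentile of 10000 random circRNA probe lists of like signal, with *RAD54B* and *PIMREG* going the other way, and a difference between the cultures themselves was not tested.

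The unadjusted list of 22 circRNA probes held 21 with higher means with oxLDL. The scaling point stays open as a source of that share. With the 75th percentile taken over detected probes, 47.6% of the 21 probes on the list called afresh were higher, but this scaling lowers all probes by nearly the same amount (a median of -0.35 on the log2 scale, where the smallest of the 21 rises was 1.37), so the outcome follows from the shift and decides nothing. A wider range of signal on the oxLDL arrays also stays open, since 17 of the 22 probes were among the 190 brightest probes tested; scalings that equalise the range remove this by construction and decide nothing, and they cannot tell labelling or hybridisation from a rise of abundant circRNAs with oxLDL.

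With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. By treatment, 0 circRNA probes passed the adjusted threshold, and the highest other split gave 127. All 10 splits gave at least as many, which a count of 0 fixes in advance, so it decides nothing. For the unadjusted list of 22 probes, 5 splits, the real one included, gave at least as many and the highest other gave 861. For the mRNA probes, 0 passed, which again all 10 splits must reach, and the highest other gave 5. The counts of 127 and 861 belong to the split of control replicates 1 and 2 with oxLDL replicate 1 against the rest. They point to a structure among the arrays, and cannot tell the samples from the slide position as its source. With quantile normalization this split gave 0 past the adjusted threshold and 799 at an unadjusted p under 0.05. It follows the outer and inner slide columns, and with the slide column as a block the treatment gave 0 circRNA probes past the adjusted threshold and 98 on the unadjusted list.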

How the results depend on the processing

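The mRNA comparison, the fit within slide row 1 and the fit without both control replicate 3 and oxLDL replicate 1 were chosen after the data were seen. The count of 0 circRNA probes past the adjusted threshold was also 0 under each alternative run, at an adjusted p under 0.1 included. The count of 0 mRNA probes was 0 under each alternative run except without both control replicate 3 and oxLDL replicate 1, where it was 2 (*EXO1* and *MOCOS*). That fit keeps controls from outer and oxLDL from inner slide columns only, after leaving out arrays chosen for their correlations, so it cannot separate treatment from column, and the 2 controls left were not well above background for *MOCOS*. The higher mean share of probes well above background with oxLDL (3.09 percentage points) kept its sign, with 1.09 for the positive and significant call and 0.031 to 5.65 with a replicate left out; without oxLDL replicate 1 the difference was 0.031, without oxLDL replicate 2 it was 5.65, without control replicate 2 it was 5.32 and without control replicate 3 it was 1.39. The cause was not tested for the changes below. Signal over background limits the whole comparison, since 2871 of 5397 circRNA probes were not well above background on any array. The filter for tested probes was also met by 2 of 40 negative sequence probes. The fit of array weights stopped before it reached its tolerance. No alternative from the plan was left out except those that need circRNA names.

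The unadjusted list of 22 circRNA probes had 12 with quantile normalization, 12 with cyclic loess, 11 with normexp and quantile normalization, 14 with the authors' value table, 46 with normexp and the 75th percentile, 119 with no filter on dim probes (more probes tested), 119 with array weights, 98 with the slide column as a block, 52 within slide row 1 and 464 without both control replicate 3 and oxLDL replicate 1. With a replicate left out it ranged from 4 to 70: 5 without control replicate 1, 70 without control replicate 3, 57 without oxLDL replicate 2 and 4 without oxLDL replicate 3. With the replicate number as a block it had 35, and 0 circRNA probes and 0 mRNA probes passed the adjusted threshold. Same-numbered arrays deviated together at r = 0.78 and 0.27 for numbers 1 and 3 and at -0.65 for number 2. Both arrays of number 1 lay in outer slide columns and both of number 3 in inner columns, while number 2 had an outer and an inner array. The signs follow these positions, so the correlations cannot show whether the numbers pair the samples.

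The 4 named circRNA probes kept their sign under each alternative run, and 0 passed the adjusted threshold. The rule that named them asks for all values of a group to lie above all values of the other. That fixed the sign in advance for fits on the same scaled values with arrays left out, weighted or blocked. Only alternatives that change the values themselves, such as scaling, background correction or the authors' value table, could have turned it. ASCRP001070 ranged from 1.30 to 4.04 and ASCRP001423 from 0.70 to 3.83. ASCRP004698 ranged from -1.38 to -0.27 and ASCRP005161 from -1.35 to -0.22, where the bound of at least 1.57-fold no longer held. Of the 12 mRNA log2 fold changes, 11 changed sign under at least 1 alternative. With the 75th percentile of detected probes, *WRN* was -0.097, *ZNF195* -0.26, *CENPE* -0.087, *PIMREG* -0.16 and *SERPIND1* -0.19. *ZNF195* was -0.064 with scaling by the median of detected probes, -0.067 with cyclic loess and -0.033 with normexp and quantile normalization, and *SERPIND1* was -0.034 with cyclic loess. With normexp and the 75th percentile, *EXO1* was 0.0031, *RHOH* 0.097 and *POLR2A* 0.16. With array weights, *EXO1* was 0.80, *SPDL1* 0.077, *PIMREG* -0.069, *RAD54B* -0.083 and *POLR2A* 0.32. With the slide row as a block, and within row 1, *EXO1* was 0.66, *SPDL1* 0.23 and *POLR2A* 0.20. With the slide column as a block, *LOXL2* was -0.067, *WRN* -0.018, *ZNF195* -0.37, *CENPE* -0.49 and *SERPIND1* -0.066. Without both control replicate 3 and oxLDL replicate 1, *EXO1* was 1.48, *SPDL1* 0.55, *RHOH* 0.017, *RAD54B* -1.002 and *POLR2A* 0.53. With a replicate left out, *ZNF195* ranged from -0.33 to 0.72, *CENPE* from -0.18 to 0.79, *EXO1* from -0.68 to 0.67, *SPDL1* from -0.47 to 0.40, *POLR2A* from -0.40 to 0.23, *RAD54B* from -0.27 to 1.57 and *SERPIND1* from -0.040 to 0.29.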

Other observations

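The test in this part was chosen after the arrays had been compared with each other. Slide columns 1 and 2 each hold an array of both treatments, which gives 2 differences between oxLDL and control from separate arrays: oxLDL replicate 1 minus control replicate 2, and oxLDL replicate 2 minus control replicate 3. Across 1896 circRNA probes, which are not independent replicates, these differences correlated at a Pearson r of 0.218 and a Spearman rho of 0.332, and at 0.17 and 0.297 with quantile normalization. In column 1, 64 probes were at least 2-fold higher with oxLDL, in column 2, 387, and 26 were so in both, where independent lists would share 13.1. With quantile normalization the shared number was 18, against 11.7. Changes of at least 2-fold in opposite directions were seen for 5 probes, and for 9 with quantile normalization. The numbers for independent lists take all probes as alike. Probes that vary more between arrays for any reason could also raise the shared number. A hypothesis is that part of the change with oxLDL is shared by both columns, which may lie hidden under the larger differences between arrays. In both columns the oxLDL array lay in slide row 1 and the control array in row 2, so treatment and row cannot be told apart in these differences. The correlation of 0.218 is above 0, as the hypothesis needs. With 1 array per treatment in each column, arrays that differ for other reasons could give the same, and the design has no further pair to decide it.

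Among the sequences that carry no gene name, 11 of 15 circRNA control probes of the array maker were well above background on at least 3 arrays. AS_circRNA_control6 was at 6.37, 5.63 and 5.16 on control replicate 3 and oxLDL replicates 2 and 3, and at 4.54, 4.69 and 3.74 on control replicates 1 and 2 and oxLDL replicate 1. AS_circRNA_control12 went the other way, at -0.25, 1.42 and 0.47 on the first 3 of these arrays and at 2.64, 2.16 and 2.15 on the others.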
